A study of Mus musculus with 11 samples.

How the data were processed

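RNA from 11 mammary tumours of MMTV-Neu+/- mice was measured on 2-colour oligonucleotide arrays, 5 tumours from mice given dimethylbenzanthracene (DMBA) and 6 from mice without it. Each array compared a tumour with a common reference RNA from whole mouse. The series design gives 19 samples, and the p53 knockout and rexinoid samples of the series title were not analysed here. The labels gave each tumour its group, and tumours were numbered in accession order within a group (DMBA 1 to 5, untreated 1 to 6), so a number only names a tumour. The array titles of DMBA 3 and DMBA 4 share a number, which the labels do not explain. They were used as separate tumours, with their mean as an alternative. The labels do not say that the tumours came from separate mice, so the p-values here measure only the spread between these samples, which may be technical.

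The values used are log2 ratios as deposited, in 2 tables. All DMBA-treated tumours lie in a table of 45220 array features, and all untreated tumours in another of 22575 features. How the authors corrected the background, normalized the arrays and filtered the features is not given in the sources used here. The log base is not stated either. It was taken as log2, because values from -10.70 to 8.37 would be too wide a range for log10 ratios of a 16-bit scanner. No value was missing. Array medians lay between -0.013 and 0.008, so the arrays appear centred, and the standard deviation (SD) of an array's values lay between 1.32 and 1.45. Exact zeros numbered 427 to 1035 per array in the DMBA table and 83 to 157 in the untreated table, and were used as they are. No signal or background values were used here, so the signal behind a ratio is unknown, and the number of arrays is the limit on precision that can be stated.

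The labels give the dye of the reference channel, but the dye field of the tumour channel holds the name of a kit. The direction of the ratio was therefore read from 3 lists of organ genes that a whole mouse reference holds and a mammary tumour should lack. On the DMBA arrays the median log2 ratio lay between -4.03 and -3.50 for the liver list, between -3.93 and -2.91 for the skeletal muscle list and between -2.46 and -2.09 for the brain list. On the untreated arrays the ranges were -4.39 to -3.94, -3.71 to -3.14 and -3.97 to -3.67. Tumour over reference is thus the likely direction on every array, and all signs below rest on it. These 3 lists served only for that and are not counted among the results.

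Features were named through the platform annotation, with symbols brought up to date through Entrez gene identifiers in a gene table of assembly GRCm38.p6. In the DMBA table, features with a single symbol numbered 33653, while 56 had several and 11511 had none listed; 33517 were matched. In the untreated table the numbers were 18658, 30, 3887 and 18445. No matched symbol changed (0 in each table). Features with several symbols or none were left out. Features of a gene were averaged on each array, which gave 19087 and 16887 genes, 16351 of them in both tables. Several features were averaged for 8343 genes of the DMBA table and for 1247 of the untreated table. A gene needed values on at least 4 arrays.

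Each group was tested against the reference in its own table with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes, two-sided test of the mean log2 ratio against 0, Benjamini-Hochberg adjustment over all genes tested). A gene was called at an adjusted p under 0.05 and counted again where the mean log2 ratio was at least 1 in size. Fold values are 2 to the power of the size of the mean log2 ratio. Before the data were examined, 30 gene lists for cell types, pathways and programmes were fixed. Each was tested against all other genes with camera from limma (preset correlation of 0.01), with Benjamini-Hochberg adjustment over the lists of a group. The estimated-correlation form of camera is given beside each call, and the number of members called is given over all genes and adjusted over the list alone. A few genes stand in more than 1 list, such as Thy1 (fibroblast, and T and NK cell), Jag2 (basal, and Notch), Ltf (alveolar, and neutrophil), Xbp1 (hormone-sensing, and unfolded protein response) and Btg2 (p53, and immediate early).

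No test was made between DMBA-treated and untreated tumours, since the group and the table cannot be told apart. Group means were set side by side instead. A gene was said to stand apart where the values of the groups did not overlap and the means differed by at least 1 on the log2 scale. Chance alone, with no effect and no table difference, would part 0.433% of genes without overlap. For gene lists, the median difference over members was placed as a percentile among 10000 random lists of the same size matched on mean log2 ratio.

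The genes named were chosen by a rule fixed before the data were examined. In each comparison with the reference these were Erbb2, the 10 called genes with the highest and the 10 with the lowest mean log2 ratio and the same sign on every array, and up to 4 members with the smallest adjusted p in each list that passed. Side by side, the rule took the 12 genes with the largest difference in each direction among those standing apart, and up to 4 members of each of the 6 lists with the largest median difference. For spread, it took the 10 genes of each group with the largest SD. Clone and predicted-gene names were passed over. Where members of lists that did not pass, or other genes, are named in the closing part, this was chosen after their values were seen. Rbp4, Krt27, Epha4 and Hbb-y, which run against the difference of their lists, were also added outside the rule, after their values were seen. So were Krt19, Sox10, Itgb4 and Oxtr, which run against the direction of their lists.

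Alternatives fixed beforehand were median-centred arrays, quantile normalization within a table, the median over features or a single feature per gene, filters on missing values, a trended robust prior, a test against 1.5-fold (treat), each replicate left out in turn, the average of the tumours sharing a title number, an estimated correlation, the directional fry test, list ranks, other scalings between the tables, genes with 1 feature in each table, and minimum differences of 1.5 and 4 times. Averaging features per accession first, leaving out untreated 2 and 6 together, leaving out genes close to the reference on every array of a table, the preset correlation with the degrees of freedom of the arrays, and the 20-point threshold of the percentile scaling were added after seeing the data.

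The steps were tested on simulated data with 200 changed genes. In the DMBA simulation over 19087 genes, limma recovered 62% of genes changed by 1 on the log2 scale and 92% of those changed by 2, and 6.1% of calls were false. In the untreated simulation over 16887 genes it recovered 91% and 99%, with 5.0% of calls false. The shifted list was recovered in both, but 50% of the lists that passed there were false. In 40 simulations with no shifted list, a list passed in 3 for the DMBA table and in 1 for the untreated table; these simulations hold independent genes, so they do not test the correlation between members. The side-by-side step over 16351 genes recovered 94.5% of genes changed by 2, and 4.5% of the genes it found were false. This simulation holds no difference between the tables or their features. Its 4.5% is therefore not the share of false genes among those standing apart in the data. The columns of the tables all belonged to mapped samples.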

Results

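The series concerns mammary tumours that arise with the carcinogen DMBA in mice that carry the Neu oncogene, the rat form of Erbb2, under a mammary promoter. DMBA is a polycyclic hydrocarbon that binds the aryl hydrocarbon receptor (AhR) and is turned into DNA-damaging products. The data are log2 ratios of tumour RNA over a whole mouse reference RNA for 5 DMBA-treated and 6 untreated tumours of MMTV-Neu+/- mice. A ratio places a gene in the tumour against its level in a pool of all mouse tissues, not against normal mammary gland. Values are given as means ± SD over the tumours of a group.

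Milk protein genes led the genes above the reference in DMBA-treated tumours (n = 5). Csn2, the beta-casein gene, was at a log2 ratio of 6.53 ± 1.09, which is 92.7-fold (adjusted p = 1.2e-05), Csn1s2a at 6.24 ± 0.60 (adjusted p = 1.55e-06) and Csn3, the kappa-casein gene, at 5.60 ± 0.16 (adjusted p = 9.49e-07). Next came Gabrp, a subunit of the GABA-A receptor, at 5.45 ± 0.27, C5ar2, a receptor for complement fragments, at 5.25 ± 0.85, Apol9a at 4.97 ± 1.5 and Ano1, a calcium-activated chloride channel, at 4.95 ± 0.34. Alkal2, a ligand of the ALK receptor, reached 4.76 ± 0.62, Plet1 4.71 ± 0.23 and Mansc1 4.58 ± 0.11. The adjusted p of these last 7 genes lay between 9.49e-07 and 0.000212.

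Among the 10 lowest genes of DMBA-treated tumours (n = 5), Itm2a was at -7.27 ± 0.54, the muscle gene Atp1b4 at -7.11 ± 0.47, and Myot, a sarcomere protein, at -6.49 ± 0.71. The liver genes Afp, Fabp1, Pck1 and Fgg were at -6.96 ± 0.47, -6.75 ± 0.46, -6.63 ± 0.47 and -6.41 ± 0.46. Cstdc6 stood at -7.12 ± 0.34, and Sostdc1, an antagonist of BMP signals, at -6.40 ± 0.50. Lum, a collagen-binding proteoglycan, was at -6.57 ± 1.77 and varied most, from -8.26 to -4.20. Fgg stands in the liver list from which the direction of the ratio was read, so its sign is no result of its own. Adjusted p-values of these 10 genes lay between 9.49e-07 and 0.000116.

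Erbb2, the endogenous counterpart of the transgene, was above the reference in all 5 DMBA-treated tumours, at 1.52 ± 0.17 or 2.86-fold (adjusted p = 2.5e-05), with single tumours between 1.32 and 1.70. This mean covers 11 features that did not read alike. Averages of 10 features lay between 0.93 and 1.39, and the other feature read 4.54 ± 0.50. Each feature counts equally, so the mean lies near these 10. Whether they are repeats of 1 reading was not examined, so they cannot be taken as 10 independent readings. In the untreated tumours Erbb2 has a single feature, which read 2.74 ± 1.03 (n = 6, 6.67-fold, adjusted p = 6.78e-05). There 5 tumours lay between 2.40 and 3.56, and untreated 2 lay at 0.86. As the tables have different features, the Erbb2 means of the groups cannot be compared. Whether a feature reads the rat transgene is not given in the sources used here.

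**Figure D1:**
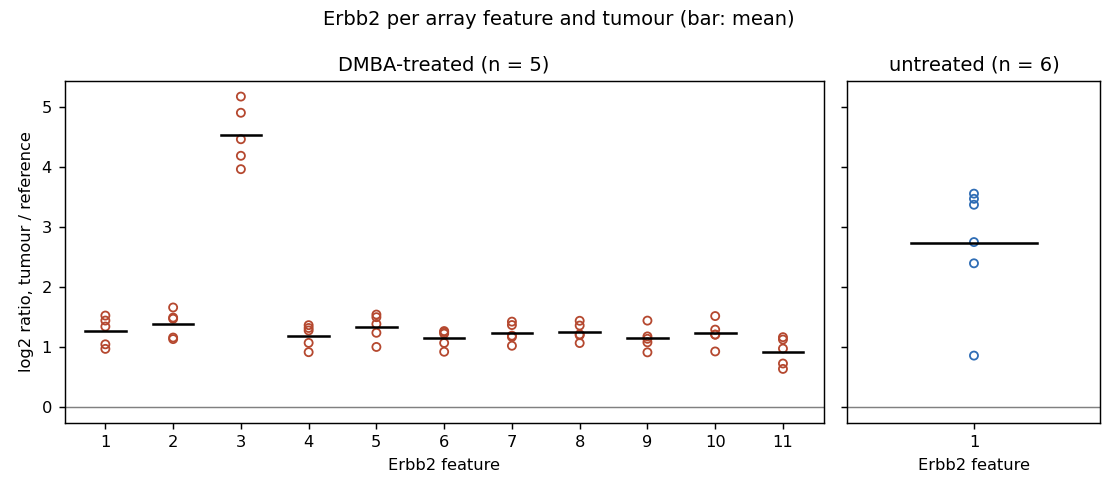
Log2 ratio of tumour over reference for each Erbb2 feature (horizontal axis), with 1 point per tumour and a bar at the mean. In the DMBA table (n = 5) 10 features average 0.93 to 1.39 and 1 averages 4.54; the only feature of the untreated table (n = 6) averages 2.74.

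Over all 19087 genes of the DMBA table, 11031 were called (57.8%), 4974 higher and 6057 lower than the reference. At least 2-fold, 1579 were higher and 3581 lower. Against a ratio of 1.5-fold, 5082 genes were called, so many of the calls are small in size.

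In the DMBA-treated tumours 6 of the 30 lists were above the reference and 11 below it (n = 5). With an estimated correlation 0 of these calls held. Member counts are over all genes; adjusted over the list alone they were the same unless another count is given.

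Luminal and pan-epithelial genes, which encode junction proteins and keratins of lining epithelium, had a median log2 ratio of 1.85. Of 19 members 15 were called higher and 1 lower (camera adjusted p = 1.74e-06, and adjusted p = 0.259 with an estimated correlation). The lower member was the keratin Krt19, at -3.50 ± 0.67. Marveld3, a tight junction protein, was at 3.44 ± 0.11, the adhesion molecule Epcam at 3.23 ± 0.17, the splicing factor Esrp1 at 3.13 ± 0.13 and Cldn3 at 2.69 ± 0.06 (n = 5). Alveolar and milk genes had a median of 2.68, with 15 of 22 higher and 2 lower (16 and 2 adjusted over the list alone; adjusted p = 2.37e-06, and adjusted p = 0.34 with an estimated correlation). Besides Csn3, the alveolar transcription factor Elf5 was at 4.04 ± 0.19, Muc15 at 4.48 ± 0.25 and Lalba, which encodes alpha-lactalbumin, at 2.96 ± 0.10.

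Antigen presentation, interferon response, MAPK output and unfolded protein response lists were also high in the DMBA-treated tumours. For antigen presentation the median was 2.23 and 12 of 16 genes were higher, 1 lower (13 and 1 adjusted over the list alone; adjusted p = 1.44e-05, and adjusted p = 0.34 with an estimated correlation). The class I genes H2-D1 and H2-K1 were at 3.95 ± 0.34 and 2.77 ± 0.24, the class II chaperone gene H2-DMb1 at 3.48 ± 0.19 and the peptide transporter gene Tap2 at 2.72 ± 0.30 (n = 5). Interferon response genes had a median of 1.70 with 13 of 18 higher and 0 lower (adjusted p = 0.000147, and adjusted p = 0.503 with an estimated correlation), among them Oas1a at 3.10 ± 0.67, Gbp2 at 2.53 ± 0.63, Ifih1 at 2.46 ± 0.99 and Ddx58 at 1.89 ± 0.65. Macrophage, T and NK cell, and B and plasma cell lists did not pass, with medians of -0.21, -0.76 and -0.59 (adjusted p = 0.893, 0.172 and 0.121), and the endothelial, erythroid and fibroblast lists beside them were low. Genes of MAPK output, induced by the kinase cascade downstream of ERBB receptors, had a median of 1.31 with 13 of 16 higher and 1 lower (adjusted p = 1.55e-05, and adjusted p = 0.239 with an estimated correlation). The ETS factors Etv1 and Etv5 were at 3.06 ± 0.19 and 2.45 ± 0.12, Phlda1 at 3.06 ± 0.27 and the receptor gene Epha2 at 3.36 ± 0.32. Unfolded protein response genes had a median of 1.05 with 10 of 16 higher and 1 lower (adjusted p = 0.00018, and adjusted p = 0.391 with an estimated correlation). Their transcription factor Xbp1 was at 3.10 ± 0.30, Sdf2l1 at 2.86 ± 0.38, Pdia4 at 2.67 ± 0.22 and the chaperone gene Calr at 1.60 ± 0.21.

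Basal and squamous markers were below the reference in the DMBA-treated tumours (n = 5). The basal and myoepithelial median was -1.92, with 3 of 19 members higher and 15 lower (3 and 16 adjusted over the list alone; adjusted p = 0.000157, and adjusted p = 0.34 with an estimated correlation). Cnn1, a smooth muscle protein, was at -4.59 ± 0.17, Lgals7 at -3.39 ± 0.31 and the keratins Krt5 and Krt15 at -2.81 ± 0.11 and -2.65 ± 0.16. The 3 higher members were Sox10 at 3.21 ± 0.39, Itgb4 at 1.77 ± 0.10 and Oxtr at 0.80 ± 0.64. Squamous and cornified genes had a median of -2.66 with 0 of 21 higher and 19 lower (adjusted p = 2.22e-07, and adjusted p = 0.259 with an estimated correlation), including Lor, the loricrin gene, at -4.90 ± 0.36, Krtdap at -3.60 ± 0.31, Klk7 at -3.57 ± 0.25 and Krt10 at -3.17 ± 0.20. Skin and hair keratin genes had a median of -2.89 with 0 of 10 higher and 9 lower (adjusted p = 6.05e-05, and adjusted p = 0.34 with an estimated correlation), with Krt25, Krt71, Krt33a and Krt35 at -4.59 ± 0.38, -4.16 ± 0.26, -4.15 ± 0.18 and -2.92 ± 0.21.

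Stromal lists lay below the reference as well (n = 5). Adipocyte genes had a median of -4.17 with 0 of 14 higher and 13 lower (adjusted p = 6.49e-07, and adjusted p = 0.34 with an estimated correlation), such as the lipid droplet gene Plin1 at -4.41 ± 0.18, Ucp1 at -4.16 ± 0.18 and the adiponectin gene Adipoq at -4.08 ± 0.20. Fibroblast and matrix genes had a median of -2.73 with 0 of 18 higher and 17 lower (18 lower adjusted over the list alone; adjusted p = 8.51e-07, and adjusted p = 0.377 with an estimated correlation), with the proteoglycan genes Ogn and Dcn at -4.25 ± 0.37 and -4.10 ± 0.48 and the collagen genes Col1a2 and Col6a1 at -3.53 ± 0.49 and -2.19 ± 0.30. EMT regulators and mesenchymal genes had a median of -1.86, 0 of 18 higher and 16 lower (adjusted p = 1.37e-05, and adjusted p = 0.404 with an estimated correlation). Snai2 was at -4.11 ± 0.54, Twist2 at -4.08 ± 0.33, Twist1 at -3.04 ± 0.48 and Zeb2 at -2.15 ± 0.23, all transcription factors of the mesenchymal state. The endothelial median was -0.94 with 0 of 16 higher and 14 lower (adjusted p = 0.000568, and adjusted p = 0.468 with an estimated correlation); the tight junction gene Cldn5, Vwf, the receptor gene Tek and Egfl7 were at -2.52 ± 0.52, -2.0 ± 0.34, -1.76 ± 0.26 and -1.73 ± 0.35.

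Neutrophil, erythroid, Wnt target and AhR lists were also low (n = 5). Neutrophil and granulocyte genes had a median of -2.73 with 0 of 14 higher and 13 lower (adjusted p = 1.46e-05, and adjusted p = 0.259 with an estimated correlation), with S100a9 at -5.31 ± 0.45, Camp at -5.29 ± 0.34, S100a8 at -5.26 ± 0.43 and Mmp9 at -3.40 ± 0.23. For erythroid genes the median was -2.12 with 0 of 10 higher and 9 lower (adjusted p = 0.000157, and adjusted p = 0.34 with an estimated correlation), among them Tal1 at -3.66 ± 0.27, Slc4a1 at -3.54 ± 0.41, Epb42 at -3.02 ± 0.09 and Klf1 at -2.74 ± 0.25. Wnt targets had a median of -1.88 with 2 of 16 higher and 12 lower (adjusted p = 0.000847, and adjusted p = 0.34 with an estimated correlation). Wif1, Axin2, Nkd1 and Dkk1, which all dampen Wnt signals, were at -4.77 ± 0.63, -4.10 ± 0.55, -3.89 ± 0.38 and -3.07 ± 0.22. AhR targets and genes of carcinogen metabolism had a median of -0.98 with 1 of 15 higher and 10 lower (2 and 10 adjusted over the list alone; adjusted p = 0.0467, and adjusted p = 0.377 with an estimated correlation). Sult1a1, a sulfotransferase, was at -4.81 ± 0.33, Gsta1 at -3.57 ± 0.35, Tiparp at -2.45 ± 0.22 and the hydrocarbon-oxidizing Cyp1a1 at -2.37 ± 0.30. This AhR call ended with a single feature per gene, with quantile normalization, and without DMBA 4 or DMBA 5, where its median was -1.05, -0.99, -0.93 and -1.02.

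Among the genes named in this group, features differed most for Klk7 (3 features, averages from -5.66 to -2.23) and Zeb2 (8 features, -3.75 to -0.39), besides Erbb2.

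In untreated tumours (n = 6) the highest genes were the caseins Csn1s2a at 5.65 ± 0.64, or 50.4-fold above the reference (adjusted p = 1.74e-08), and Csn1s1, the alpha-casein gene, at 5.04 ± 0.64 (adjusted p = 3.74e-08). Csn2 stood lower among the 10 highest, at 4.08 ± 1.12 (adjusted p = 7.52e-06). C5ar2 was at 4.64 ± 0.61, Galnt3, which starts mucin-type glycosylation, at 4.62 ± 0.35, Plet1 at 4.50 ± 0.39 and Ano1 at 4.42 ± 0.18. Gabrp reached 4.28 ± 0.54, the acyl-CoA synthetase gene Acsl4 4.23 ± 0.52 and Mansc1 3.99 ± 0.35. For these 7 genes the adjusted p lay between 6.4e-10 and 5.14e-08. Of the 10 highest genes, 7 (Csn1s2a, Csn2, C5ar2, Plet1, Ano1, Gabrp and Mansc1) were also among the 10 highest of the DMBA-treated tumours. Apol9a and Alkal2, among the 10 highest there, have no value in the untreated table and so could not be shared.

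At the low end the untreated tumours had Atp1b4 at -7.39 ± 0.37, the urea cycle gene Cps1 at -7.17 ± 0.22, Fabp1 at -7.07 ± 0.42 and Myot at -7.04 ± 0.19 (n = 6). Rbfox1, a splicing factor of nerve and muscle, was at -6.80 ± 0.23, Amelx, the enamel protein amelogenin, at -6.76 ± 0.27, the muscle gene Smpx at -6.68 ± 0.10 and Itm2a at -6.60 ± 1.14. The plasma protein genes Rbp4 and Ambp were at -6.52 ± 0.22 and -6.37 ± 0.27. Cps1 and Ambp stand in the liver list that gave the direction of the ratio. The adjusted p of these 10 genes lay between 3.73e-10 and 2.62e-07. Over all 16887 genes, 10281 were called (60.9%), 4863 higher and 5418 lower; at least 2-fold, 1148 were higher and 2642 lower. Against 1.5-fold, 4056 genes were called.

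In untreated tumours 7 of the 30 lists were above the reference and 10 below it (n = 6). Only the squamous call held with an estimated correlation. Counts adjusted over the list alone were the same unless given.

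Luminal and pan-epithelial genes had a median of 1.90 with 16 of 19 higher and 1 lower (camera adjusted p = 1.22e-06, and adjusted p = 0.0594 with an estimated correlation). The lower member was again Krt19, at -3.84 ± 0.44. Marveld3 was at 3.33 ± 0.30, the membrane protease gene St14 at 3.10 ± 0.21, the protease inhibitor gene Spint2 at 3.04 ± 0.28 and Cldn3 at 2.68 ± 0.18 (n = 6). Alveolar and milk genes had a median of 1.77 with 16 of 21 higher and 2 lower (adjusted p = 7.59e-06, and adjusted p = 0.0594 with an estimated correlation), with Elf5 at 3.87 ± 0.31, Aldoc at 3.29 ± 0.31 and Lalba at 3.14 ± 0.31. Mitosis genes passed by a small shift. Their median was 0.31, with 10 of 19 higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 0.00603, and adjusted p = 0.36 with an estimated correlation), and the kinase gene Plk1 was at 0.91 ± 0.19, Bub1b at 0.56 ± 0.20, Cdk1 at 0.56 ± 0.19 and Tpx2 at 0.52 ± 0.21. The last 3 of these genes lost their call against 1.5-fold.

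Antigen presentation genes had a median of 1.97 with 13 of 15 higher and 1 lower (adjusted p = 2.06e-05, and adjusted p = 0.18 with an estimated correlation), including H2-DMb1 at 3.39 ± 0.23, Tap2 at 2.19 ± 0.60, H2-K1 at 1.97 ± 0.28 and Tapbp at 1.83 ± 0.37 (n = 6). For interferon response genes the median was 1.02 with 13 of 17 higher and 0 lower (13 and 1 adjusted over the list alone; adjusted p = 0.00159, and adjusted p = 0.512 with an estimated correlation). Gbp2 was at 2.13 ± 0.34, Ifih1 at 2.10 ± 0.90, Oasl2 at 1.62 ± 0.94 and Ddx58 at 1.02 ± 0.28. MAPK output genes had a median of 0.87 with 13 of 17 higher and 2 lower (adjusted p = 0.000113, and adjusted p = 0.0594 with an estimated correlation); Ier3 was at 3.47 ± 0.54, Etv1 at 2.72 ± 0.05, Phlda1 at 2.54 ± 0.21 and the phosphatase gene Dusp6, which switches ERK off, at 2.22 ± 0.32. Unfolded protein response genes had a median of 0.74 with 10 of 15 higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.00164, and adjusted p = 0.124 with an estimated correlation), with Xbp1, Pdia4, Hsp90b1 and Hspa5 at 2.64 ± 0.36, 1.88 ± 0.25, 1.23 ± 0.35 and 1.17 ± 0.22.

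Squamous and cornified genes had a median of -1.95 in untreated tumours, with 1 of 21 higher and 19 lower (1 and 20 adjusted over the list alone; adjusted p = 6.23e-08, and adjusted p = 0.0402 with an estimated correlation). Klk7 was at -5.12 ± 0.18, Lor at -4.76 ± 0.25, Krt10 at -4.18 ± 0.26 and Flg, the filaggrin gene, at -3.87 ± 0.14 (n = 6). The basal and myoepithelial median was -2.08 with 3 of 18 higher and 15 lower (adjusted p = 0.000763, and adjusted p = 0.109 with an estimated correlation), and Cnn1, Krt5, the smooth muscle myosin gene Myh11 and Krt15 were at -4.64 ± 0.25, -3.65 ± 0.12, -3.23 ± 0.07 and -3.02 ± 0.18. The 3 higher members were Sox10 at 2.85 ± 0.204, Itgb4 at 1.77 ± 0.37 and Oxtr at 1.36 ± 0.695. Skin and hair keratin genes had a median of -1.84 with 0 of 11 higher and 10 lower (adjusted p = 5.18e-05, and adjusted p = 0.0994 with an estimated correlation), with Krt28 at -5.28 ± 0.16, Krt27 at -3.64 ± 0.20, Krt35 at -3.30 ± 0.18 and Krt71 at -2.06 ± 0.17.

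Stromal genes were low in untreated tumours too (n = 6). The adipocyte median was -4.0 with 0 of 14 higher and 13 lower (adjusted p = 6.23e-08, and adjusted p = 0.0994 with an estimated correlation), and Cidec, Car3, the glucose transporter gene Slc2a4 and Adipoq were at -5.66 ± 0.24, -5.21 ± 0.31, -4.98 ± 0.37 and -4.39 ± 0.10. For fibroblast and matrix genes the median was -3.18 with 1 of 18 higher and 16 lower (adjusted p = 1.34e-07, and adjusted p = 0.25 with an estimated correlation), with Dcn at -4.92 ± 0.46, Col5a1 at -4.59 ± 0.41, Ogn at -4.57 ± 0.11 and Fap at -3.31 ± 0.32. EMT regulators and mesenchymal genes had a median of -2.73 with 1 of 18 higher and 14 lower (adjusted p = 1.28e-05, and adjusted p = 0.0994 with an estimated correlation), including the cadherin gene Cdh11 at -4.60 ± 0.41, Snai2 at -3.97 ± 0.29, Twist1 at -3.88 ± 0.35 and Twist2 at -3.11 ± 0.14. The endothelial median was -1.23 with 0 of 16 higher and 15 lower (adjusted p = 2.14e-05, and adjusted p = 0.117 with an estimated correlation); Cldn5, Egfl7, Tek and Robo4 were at -3.30 ± 0.38, -2.34 ± 0.29, -2.12 ± 0.24 and -1.59 ± 0.30.

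Neutrophil and granulocyte genes had a median of -2.14 with 0 of 13 higher and 12 lower (adjusted p = 3.28e-05, and adjusted p = 0.0594 with an estimated correlation), with S100a9 at -5.81 ± 0.16, S100a8 at -5.51 ± 0.42, Camp at -5.48 ± 0.14 and the myeloperoxidase gene Mpo at -3.82 ± 0.21 (n = 6). Erythroid genes had a median of -2.11 with 0 of 10 higher and 8 lower (adjusted p = 0.000736, and adjusted p = 0.15 with an estimated correlation), among them Slc4a1 at -3.84 ± 0.21, Tal1 at -3.15 ± 0.27, Klf1 at -2.34 ± 0.21 and Epb42 at -1.88 ± 0.38. Wnt targets had a median of -2.10 with 2 of 15 higher and 12 lower (adjusted p = 0.000394, and adjusted p = 0.0994 with an estimated correlation). Apcdd1, Sp5 and the stem cell receptor gene Lgr5 were at -4.55 ± 0.18, -2.55 ± 0.24 and -2.42 ± 0.15, while Rnf43, a ligase that removes Wnt receptors, was above the reference at 2.36 ± 0.17. The AhR list did not pass here, with a median of -0.49 (adjusted p = 0.141).

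**Figure D2:**
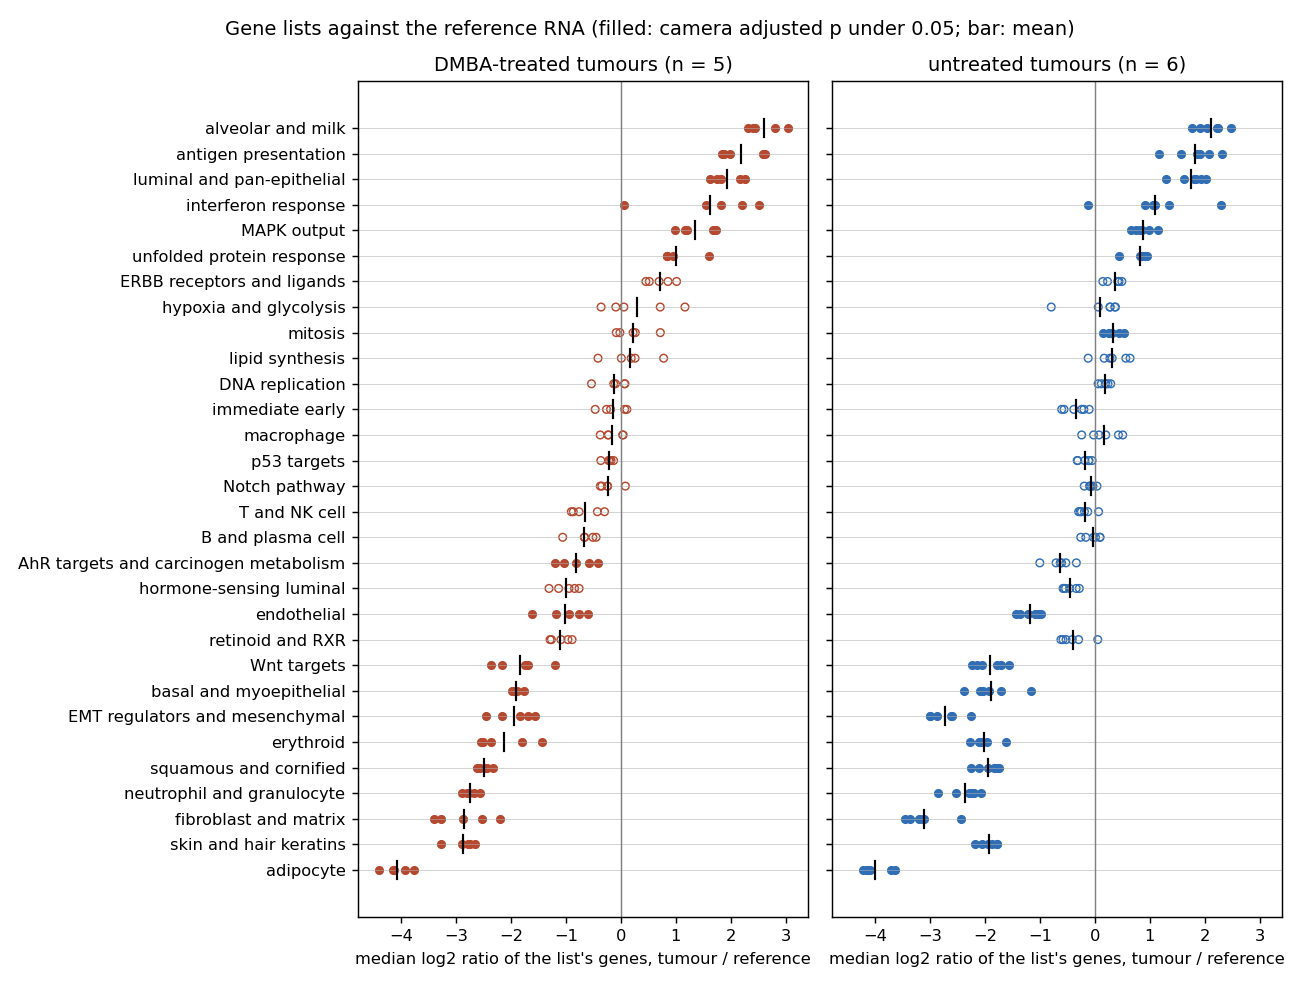
Median log2 ratio of each list's genes in each tumour (points), with the mean over tumours as a bar, for DMBA-treated (left, n = 5) and untreated tumours (right, n = 6); filled points mark lists with a camera adjusted p under 0.05. Alveolar, antigen presentation and luminal lists lie above 0 in all tumours, and adipocyte, keratin and fibroblast lists lie below 0 in all tumours.

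The groups resembled each other against the reference. Over the 16351 genes in both tables, the group means correlated across genes with Pearson's r = 0.849 and Spearman's rho = 0.775; genes are not independent replicates. Among these genes, 801 were called at least 2-fold higher in both groups, of 1404 in DMBA-treated and 1134 in untreated tumours, where independent lists would share 97.4. At least 2-fold lower in both were 2143 genes, of 3212 and 2572, where independent lists would share 505.2. Opposite calls, at least 2-fold in both groups, were made for 11 genes. All arrays were set against 1 reference RNA, so part of this likeness may come from the reference, and with ratios alone that part could not be simulated or split.

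DMBA-treated tumours were set beside untreated tumours without a test. The tables hold different features, and how each was normalized is not given, so a difference here may come from the tables as well as from the tumours. Higher in DMBA-treated tumours were App, the amyloid precursor gene (0.72 ± 0.22, n = 5, against -4.11 ± 0.32, n = 6), the potassium channel gene Kcnh2 (0.43 ± 1.10 against -3.80 ± 0.29), the nuclear envelope gene Syne4 (3.34 ± 0.23 against -0.76 ± 0.95) and Ctsc, a lysosomal protease (0.80 ± 0.24 against -3.19 ± 0.43). Lower were Amph, which acts in endocytosis at synapses (-5.56 ± 0.36 against 0.93 ± 0.39), Ccdc106 (-3.56 ± 0.17 against 2.50 ± 0.80), the stem cell factor gene Sox2 (-5.18 ± 1.15 against 0.06 ± 0.21) and the inhibitory transmitter transporter gene Slc32a1 (-4.54 ± 0.23 against 0.28 ± 0.24). App has 13 features in the DMBA table and 1 in the other, and with a single feature per gene its difference turned from 4.84 to -0.88.

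Further genes above in the DMBA table were Tubb3 (-1.68 ± 0.15 against -5.50 ± 0.33), Pitpnb (0.47 ± 0.25 against -3.27 ± 0.25), Nkain3 (-1.91 ± 0.66 against -5.51 ± 0.08) and Foxi1 (3.26 ± 0.38 against -0.34 ± 0.57). To these the rule added Amelx (-3.18 ± 0.21 against -6.76 ± 0.27), Ism1 (-0.17 ± 0.32 against -3.71 ± 0.28), Tmem82 (3.49 ± 0.38 against -0.03 ± 0.34) and the myosin gene Myh13 (0.91 ± 0.47 against -2.61 ± 0.09), with n = 5 and n = 6. Amelx fell to a difference of 0.85 and Nkain3 to 1.65 with a single feature per gene. Further genes below were the chloride transporter gene Slc12a5 (-4.45 ± 0.26 against 0.04 ± 0.22), Ncan (-4.70 ± 0.26 against -0.23 ± 0.31), Ms4a8a (-2.16 ± 0.13 against 2.25 ± 1.41) and Aoc1 (-5.07 ± 0.45 against -0.78 ± 0.11). The last of them were the phospholipase gene Pla2g5 (-3.64 ± 0.28 against 0.57 ± 0.23), the lens channel gene Mip (-1.63 ± 0.26 against 2.47 ± 0.90), the synaptic gene Nlgn1 (-3.78 ± 0.31 against 0.17 ± 0.31) and Mirg (-3.98 ± 0.31 against -0.02 ± 0.11). Among the 12 lower genes 6 (Sox2, Slc32a1, Slc12a5, Ncan, Nlgn1 and Mirg) lay within 0.75 of the reference on every untreated array, so their features showed almost no ratio there, while the brain list read between -3.97 and -3.67 on the same arrays. Tmem82 lay as close to the reference in the untreated table and Ism1 in the DMBA table.

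**Figure D3:**
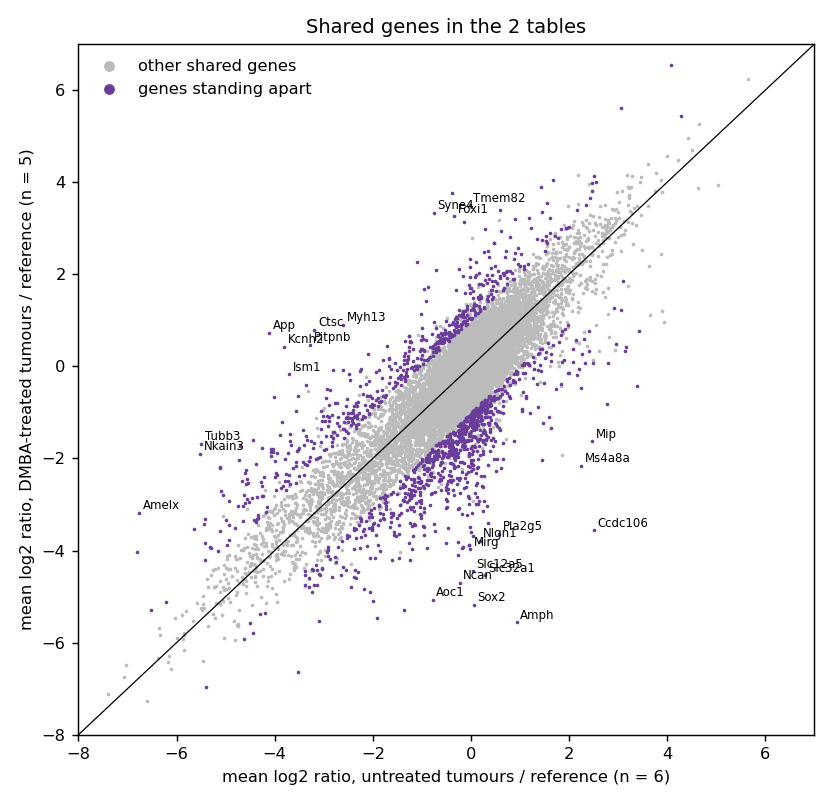
Mean log2 ratio of tumour over reference for the 16351 shared genes, untreated tumours on the horizontal axis (n = 6) and DMBA-treated tumours on the vertical axis (n = 5), with the line of equal values. Genes standing apart are in purple, 535 above and 828 below the line, and the named genes carry their symbols.

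Among gene lists, retinoid and RXR genes had the lowest percentile against random lists, with a median difference of -0.59 (percentile 0.06 of 10000 random lists, 14 of 20 members lower) and array medians that did not overlap. Of its members, Aldh1a2, an enzyme that makes retinoic acid, was at -2.65 ± 0.49 (n = 5) against -1.03 ± 0.10 (n = 6), and Nr1h3, a nuclear receptor that pairs with RXR, at -1.28 ± 0.35 against 0.15 ± 0.79. Crabp2 and Abca1 overlapped between the groups, at 0.10 ± 2.15 against 1.78 ± 0.69 and at -1.04 ± 0.65 against -0.02 ± 0.40. Without DMBA 3 the Crabp2 difference was -0.83 in place of -1.67. Rbp4 stood apart the other way, at -5.29 ± 0.22 against -6.52 ± 0.22. The AhR list had a median difference of -0.50 (percentile 1.19, 12 of 15 lower), with Gsta1 at -3.57 ± 0.35 against -2.20 ± 0.52, the receptor repressor Ahrr at -3.07 ± 0.66 against -1.98 ± 0.38, Tiparp at -2.45 ± 0.22 against -1.52 ± 0.42 and Sult1a1 at -4.81 ± 0.33 against -4.05 ± 0.30. The Sult1a1 difference of -0.76 was -0.38 with each array scaled to the mean SD. Array medians of the AhR list overlapped and averaged -0.81 against -0.64, a smaller gap than the -0.50 over members. For skin and hair keratins the difference was -0.74 (percentile 1.96, 6 of 10 lower and 4 higher, array medians apart), with Krt33a at -4.15 ± 0.18 against -1.47 ± 0.46, Krt71 at -4.16 ± 0.26 against -2.06 ± 0.17, Padi3 at -2.86 ± 0.33 against -1.23 ± 0.26 and Krt25 at -4.59 ± 0.38 against -3.29 ± 0.43. Krt27 was at -3.17 ± 0.28 against -3.64 ± 0.20. Over the settings run, the retinoid difference lay between -0.73 and -0.37, the AhR difference between -0.60 and -0.32, and the keratin difference between -1.19, over genes with 1 feature in each table, and -0.52, without DMBA 1.

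In the other direction, interferon response genes differed by 0.48 (percentile 96.97, 15 of 17 members higher), with Irf7 at 2.60 ± 1.26 against 1.55 ± 1.16, Ifit3 at 1.35 ± 1.10 against 0.42 ± 0.97, Ifit1 at 2.22 ± 1.55 against 1.32 ± 1.36 and Ddx58 at 1.89 ± 0.65 against 1.02 ± 0.28, all of which overlapped (n = 5 and n = 6). The first 3 differences moved when 1 tumour was left out. That of Irf7, 1.05, was 1.47 without DMBA 1 and 0.69 without DMBA 5. That of Ifit3, 0.93, was 1.39 without DMBA 1 and 0.61 without untreated 2. That of Ifit1, 0.90, was 1.51 without DMBA 1, 0.52 without DMBA 5 and 0.42 without untreated 2. Without untreated 2 and 6 they were 0.63, 0.60 and 0.32. With a single feature per gene the Ddx58 difference was 1.89 in place of 0.87. MAPK output genes differed by 0.38 (percentile 91.8, 12 of 16 higher), led by Epha2 at 3.36 ± 0.32 against 1.44 ± 0.96, with Etv5 at 2.45 ± 0.12 against 1.55 ± 0.39, Etv4 at 2.45 ± 0.28 against 1.65 ± 0.42 and Spry2 at 1.09 ± 0.39 against 0.42 ± 0.39. Epha4 stood apart the other way at -2.09 ± 0.98 against -0.43 ± 0.28. Erythroid genes differed by -0.45 (percentile 16.1, 7 of 10 lower), with Epb42 at -3.02 ± 0.09 against -1.88 ± 0.38 and Hba-a1, Hba-x and Hbb-bh1 at -1.87 ± 0.75 against -0.88 ± 0.16, -0.99 ± 0.62 against -0.24 ± 0.35 and -1.07 ± 0.28 against -0.56 ± 0.31. The largest difference of the list was upward, in Hbb-y at -0.97 ± 0.34 against -3.06 ± 0.98. Array medians of the erythroid list overlapped and averaged -2.13 against -2.02, a smaller gap than the -0.45 over members. Over the settings run, the MAPK difference lay between 0.21 and 0.44 and the erythroid difference between -0.53 and -0.25. Hbb-bh1 went from a difference of -0.51 to -0.28 with quantile normalization of all arrays together. The interferon difference lay between 0.12, without untreated 2 and 6, and 0.89, without DMBA 1. It was 0.24 without DMBA 2 or without DMBA 5, 0.27 without untreated 2 and 0.75 without untreated 4. Smaller median differences had percentiles as far out in the endothelial list (0.32, percentile 99.71, 14 of 16 members higher, 0.18 without DMBA 2 and 0.62 with quantile normalization of all arrays together), the EMT list (0.32, percentile 97.41, 10 of 18 higher) and the DNA replication list (-0.28, percentile 0.85, 16 of 20 lower). The EMT difference turned to -0.16 with a single feature per gene and to -0.22 over genes with 1 feature in each table. Percentiles ignore the correlation between members. For the endothelial, EMT and DNA replication lists it was estimated at 0.63, 0.69 and 0.34 in DMBA-treated tumours, and at 0.15, 0.08 and 0.08 in untreated tumours. The interferon list had the highest estimate of the 30 lists in both groups, at 0.88 in DMBA-treated and 0.74 in untreated tumours. Mitosis genes differed by -0.13 (percentile 4.97), and between -0.23 and -0.03 over the settings run. Array medians were apart for 4 of the 30 lists, the retinoid and keratin lists and also hormone-sensing luminal (-0.95 against -0.46) and B and plasma cell genes (-0.67 against -0.04). Outside this count, the brain list used for the direction was apart as well, at -2.30 against -3.81. That gap is wider than for any of these 4 lists, in genes that a mammary tumour should lack, and the median over its members was only 0.16. The B and plasma cell members differed by a median of -0.37 (percentile 4.88, 10 of 14 lower), or -0.59 without DMBA 5. For hormone-sensing luminal genes the median over members was 0.09, with 6 higher and 6 lower (percentile 61.88), which runs against the array medians.

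In all, 2978 of the 16351 shared genes (18.2%) did not overlap between the groups, where chance gives 0.433% or 70.8 genes, and 535 higher and 828 lower genes also differed by at least 1. The median size of a difference was 0.35, and 89.3% of genes differed by less than 1. Of the 1363 genes standing apart, 431 lay within 0.75 of the reference on every array of the untreated table and 118 did so in the DMBA table, a bound set after seeing the data. Without these, 371 were higher and 444 lower. Over genes with 1 feature in each table, 213 were higher and 430 lower.

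Within groups, tumours differed most in a few genes. In DMBA-treated tumours Nrg2, a ligand of ERBB receptors, had the largest SD, 4.64, with values from -4.56 to 5.25 (n = 5). Of the other 9 genes of largest SD, all were set apart by a single tumour. Nrg2 and these 9 genes each have a single feature, so no other feature checks these values. The dynein gene Dnali1 was at 6.60 in DMBA 2 and between -1.83 and -0.90 in the rest, and its SD of 3.65 fell to 0.44 without that tumour. Ninj2 (-6.98 in DMBA 2, 0.25 to 0.78 in the rest) went from an SD of 3.38 to 0.22, and Rdh16f2 (-9.71 in DMBA 2, -2.33 to -1.86 in the rest) from 3.37 to 0.22. Gabra6 was at -6.30 in DMBA 5, Sh2d4b at -6.41 and Ugt2b5 at -10.70 in DMBA 1, Btbd35f1 at -6.51 in DMBA 2, and Olfr1453 and Vmn1r14 at -5.75 and -5.91 in DMBA 3; their SDs, from 2.96 to 3.16, fell to between 0.24 and 0.90 without that tumour. In untreated tumours (n = 6) the largest SD was that of Lgals7, an epithelial galectin, 2.48, with values from -4.25 to 1.49. Emb, Dcpp1, Cpe and Ppp2r2c had SDs of 2.26, 2.26, 2.25 and 2.14, and Fetub, Pigt, Lars2, the antioxidant gene Gpx2 and the interferon-induced Ifi27l2a 2.13, 2.08, 2.07, 2.06 and 2.03. Without untreated 6, where it was at 0.64 against -4.93 to -1.71 in the rest, Dcpp1 had an SD of 1.38. Emb, Dcpp1, Ppp2r2c and Gpx2 were farthest from the group median in untreated 6, and Lgals7, Pigt and Lars2 in untreated 2. Without both tumours these SDs were 1.21, 0.57, 0.30 and 1.01, and 2.10, 1.14 and 0.76, a fall to be expected when the farthest tumour of a gene is left out. Over all genes the median SD was 0.316 in DMBA-treated and 0.277 in untreated tumours, and 906 of 19087 and 292 of 16887 genes had an SD above 1; over the 16351 shared genes these were 627 and 285. Where 1 transcript record of a gene had at least 10 features, these also scattered more on the DMBA arrays, with a median absolute deviation of 0.229 (216 records) against 0.104 on the untreated arrays (47 records). Arrays of a group correlated across genes with r between 0.823 and 0.893 for DMBA-treated and between 0.865 and 0.939 for untreated tumours. DMBA 3 and DMBA 4, whose array titles share a number, were the most alike pair of their group (r = 0.893). Their deviations from the group mean correlated across genes at -0.129, against -0.340 to -0.193 for the other pairs and -0.25 for unstructured arrays. With these 2 tumours averaged and counted as 1, 10135 genes were called in place of 11031.

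**Figure D4:**
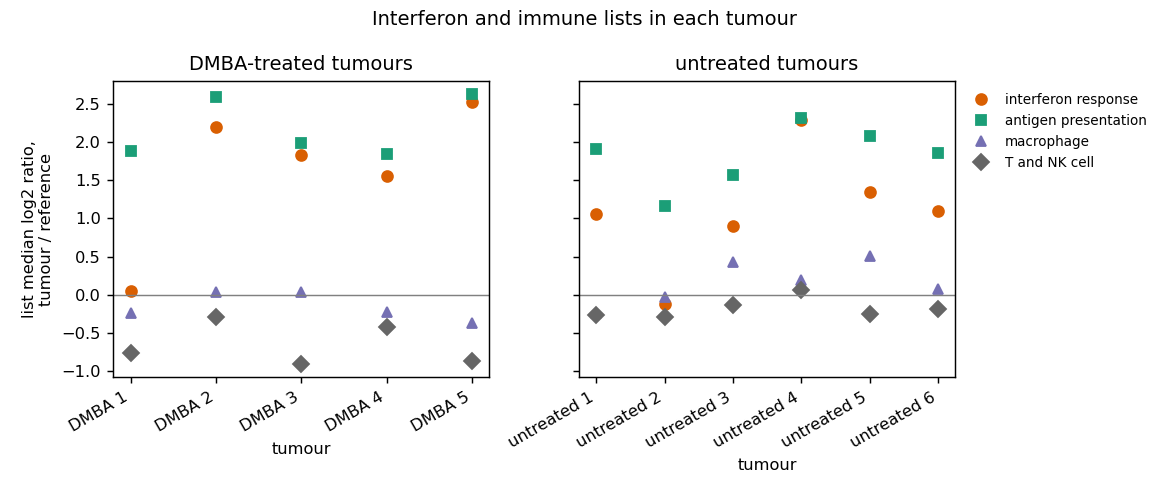
Median log2 ratio of the interferon response, antigen presentation, macrophage and T and NK cell lists in each tumour, DMBA-treated on the left and untreated on the right. The interferon list is lowest in DMBA 1 (0.05, others from 1.55 to 2.52) and in untreated 2 (-0.12, others from 0.91 to 2.29).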

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

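All tests of explanations in this part were chosen only after the results they bear on had been seen. Among 337 sets of values, covering the named genes and the lists in each group, 28 had a tumour whose gap to the nearest other tumour took up an unusually large part of the group's range (Dixon's test at 5%). Of these sets, 20 were of genes chosen for their large SD, which favours such tumours, and 9 of those are among the 28. The other 317 sets had 19, where chance gives about 1 in 20, or 15.9.

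In DMBA-treated tumours (n = 5), genes with 1 low or high tumour were C5ar2 (3.74 in DMBA 5, 5.50 to 5.77 in the rest), Sostdc1 (-5.54 in DMBA 2), Marveld3 (3.25 in DMBA 1), Muc15 (4.93 in DMBA 2), Klk7 (-3.14 in DMBA 2), Tap2 (3.24 in DMBA 5), Etv1 (3.41 in DMBA 1), Pitpnb (0.91 in DMBA 5) and Foxi1 (3.94 in DMBA 5). The genes of largest SD added Dnali1 (6.60 in DMBA 2), Ninj2 (-6.98 in DMBA 2), Rdh16f2 (-9.71 in DMBA 2), Btbd35f1 (-6.51 in DMBA 2), Sh2d4b (-6.41 in DMBA 1), Ugt2b5 (-10.70 in DMBA 1), Olfr1453 (-5.75 in DMBA 3), Vmn1r14 (-5.91 in DMBA 3) and Gabra6 (-6.30 in DMBA 5). The unfolded protein response list was highest in DMBA 5, at 1.60, with the rest between 0.84 and 0.95.

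In untreated tumours (n = 6), tumour 2 stood away for the keratin Krt15 (-2.67), S100a8 (-4.66), Apcdd1 (-4.19), Ccdc106 (0.95) and Ms4a8a (-0.53, the rest between 2.32 and 3.38). Tumour 6 stood away for Fap (-2.70) and for the fibroblast and matrix list (-2.45, the rest between -3.45 and -3.11). The hypoxia and glycolysis list was at -0.80 in tumour 3 (0.06 to 0.38 in the rest), and the unfolded protein response list at 0.44 in tumour 1 (0.82 to 0.94 in the rest).

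For 8 named genes every DMBA-treated tumour had one sign and every untreated tumour the other. These differences, which were not tested, were 4.84 for App, 3.98 for Ctsc, 3.75 for Pitpnb, 3.51 for Myh13, -4.10 for Mip, -4.21 for Pla2g5, -6.06 for Ccdc106 and -6.49 for Amph.

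The genes standing apart between the groups, 535 higher and 828 lower, may come in part from array features that read 1 gene differently. On the larger array, pairs of features for the same gene differed by a median of 0.631 (2011 pairs), 1.82 times (95% interval 1.70 to 1.95) the median of 0.347 between the tables over 8351 genes with 1 feature in each. The pairs come from other genes than those 8351, so this ratio cannot show that such features set genes apart. Genes stood apart about as often with 1 feature in each table (643 of 8351, 7.70%) as with several in the DMBA table (703 of 7864, 8.94%), so how much of the pattern such features make up stays open. The values argue against a different overall spread of ratios on the arrays, since quantile normalization of all arrays together left 0.941 times as many genes apart. DMBA treatment stays open and cannot be told apart from the table, because 0 tables hold both groups.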

How the results depend on the processing

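Settings fixed before the data were examined are given first, and those added after seeing the data are named as such. No paired analysis was possible because the labels give no replicate number that pairs tumours across the groups and no test was made between them. Each array holds its own tumour and the reference, and signal over background is unknown, so what dim features limit could not be examined. With each replicate left out in turn, the called genes numbered 9792 to 10660 for DMBA-treated tumours and 9263 to 9979 for untreated tumours, the lists passing 16 to 18 and 17 to 18, and the genes standing apart 534 to 580 higher and 827 to 935 lower. At least 2-fold, the ranges were 1552 to 1612 higher and 3519 to 3615 lower in DMBA-treated, and 1128 to 1199 higher and 2612 to 2674 lower in untreated tumours.

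Testing against 1.5-fold gave 5082 called genes in place of 11031 for DMBA-treated tumours and 4056 in place of 10281 for untreated tumours, by its own construction, since it asks for a larger change. An estimated correlation left 0 of 17 lists in DMBA-treated tumours and 1 of 17 in untreated tumours after adjustment over all lists. MAPK output in both groups and the neutrophil list in untreated tumours had estimated correlations of -0.02, -0.05 and -0.03. Their unadjusted p with an estimated correlation were 0.00797, 0.00692 and 0.00544, and the adjusted p, which also depend on the other lists, were 0.239, 0.0594 and 0.0594. That form of the test also uses fewer degrees of freedom, which alone, tried after seeing the data, left 16 and 16 lists and ended the AhR call in DMBA-treated and the mitosis call in untreated tumours. The directional fry test, which does not compare a list with other genes, passed 26 and 29 lists. A single feature per gene, the one farthest from 0, gave 1371 genes lower in DMBA-treated tumours in place of 828 and turned the differences of App (-0.88 in place of 4.84) and of the brain list (-0.18 in place of 0.16). It also turned 3 of the 30 other list differences, EMT (-0.16 in place of 0.32), fibroblast (-0.14 in place of 0.22) and neutrophil (-0.19 in place of 0.04). Genes with 1 feature in each table, a smaller set, gave 213 higher and 430 lower, a brain list difference of -0.04 and an EMT difference of -0.22, and turned the p53 and Notch differences, which lie near 0, to 0.02 and 0.002. Of the 30 list differences, 12 turned in at least 1 setting, among them EMT in 2. A minimum difference of 1.5 times gave 1129 and 1425, and one of 4 times 87 and 169. Without genes close to the reference on every array of a table, a setting added after seeing the data that leaves fewer genes, 371 were higher and 444 lower. For App and these lists the cause was not tested.

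All counts of the other settings run, including the scalings between the tables, stayed within 1.5 times of the main counts. Apart from the replicates left out in turn, their called genes ranged from 10135 to 11136 in DMBA-treated and from 9659 to 10472 in untreated tumours, and genes apart from 535 to 771 higher and 653 to 953 lower. The filters on missing values removed no gene and so say nothing. Of the settings added after seeing the data, leaving out untreated 2 and 6 gave 9659 called genes, 18 lists and 664 and 953 genes apart. Among single results, 3 gene calls (Cdk1, Bub1b and Tpx2 in untreated tumours, against 1.5-fold) and 39 list calls were lost and 27 list calls were gained, most of them by the estimated correlation and fry. Apart from these and the degrees of freedom, the AhR list of DMBA-treated tumours was lost in 4 settings. The mitosis list there was gained without DMBA 1 (median 0.23), without DMBA 3 (0.30) and with the tumours sharing a title number averaged (0.33). The ERBB list was gained with a single feature per gene in DMBA-treated tumours (1.11) and without untreated 2 and 6 in untreated tumours (0.46), and DNA replication without untreated 5 (0.25). By more than the spread between replicates, 22 list differences, 12 gene differences and 17 gene spreads moved.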

Other observations

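The tests of explanations in this part were chosen only after the results they bear on had been seen, and the tumour examined for the interferon list was redefined as the lowest of each group after a first choice, the tumour farthest from the median, had been seen. Genes named here from lists that did not pass were also chosen after their values were seen.

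ERBB receptors and ligands did not pass as a list, with a median of 0.71 in DMBA-treated tumours (adjusted p = 0.0638, n = 5) and 0.27 in untreated tumours (adjusted p = 0.141, n = 6). Some members were above the reference beside Erbb2. The ligand gene Egf was at 2.12 ± 0.30 in DMBA-treated tumours (adjusted p = 1.71e-05) and 1.95 ± 1.57 in untreated tumours (adjusted p = 0.00676), Tgfa at 1.82 ± 0.21 and 0.52 ± 0.46 (adjusted p = 1.48e-05 and 0.0177), Egfr at 0.85 ± 0.30 and 1.62 ± 0.56 (adjusted p = 0.00152 and 5.75e-05), and Grb7, an adaptor whose gene lies close to Erbb2, at 1.22 ± 0.31 and 1.04 ± 0.22. Other members were below it, with Hbegf at -1.12 ± 0.28 and -0.73 ± 0.66 (adjusted p = 0.000332 and 0.016) and Muc4 at -0.97 ± 0.36 and -0.85 ± 0.13 (adjusted p = 0.00141 and 1.97e-05). Nrg1 was at -0.67 ± 0.30 in DMBA-treated (adjusted p = 0.00475) and 0.07 ± 0.57 in untreated tumours (adjusted p = 0.778). Hormone-sensing luminal genes split by member, with medians of -1.11 (adjusted p = 0.564) and -0.37 (adjusted p = 0.408). Gata3 was at 4.39 ± 0.30 and 3.61 ± 0.29, while Tff3 was at -3.69 ± 0.25 and -4.01 ± 0.19 and Wnt4 at -2.33 ± 0.29 and -2.19 ± 0.11. Esr1 was at 2.98 ± 0.51 in DMBA-treated tumours, over 11 features with averages from 0.27 to 3.49. In untreated tumours its only feature read 0.29 ± 0.155, so these 2 means cannot be compared. The p53 target list had medians of -0.10 (adjusted p = 0.671) and -0.28 (adjusted p = 0.697), and its members also split. In DMBA-treated tumours 4 of 18 were called higher and 7 lower, and in untreated tumours 3 of 18 higher and 8 lower. Cdkn1a was low in both groups at -2.24 ± 0.72 and -1.79 ± 0.93 (adjusted p = 0.000356 and 0.000597). Ddb2 was at 0.08 ± 0.38 (adjusted p = 0.694) and 2.48 ± 1.13 (adjusted p = 0.000241).

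Proliferation lists lay close to the whole mouse pool. Mitosis genes had a median of 0.25 in DMBA-treated tumours (adjusted p = 0.0864) and of 0.31 in untreated tumours, where 10 of 19 were called higher and the list passed (adjusted p = 0.00603, and adjusted p = 0.36 with an estimated correlation), and DNA replication genes were at -0.16 (adjusted p = 0.706) and 0.19 (adjusted p = 0.0789). For hypoxia and glycolysis the medians were 0.23 (adjusted p = 0.133) and 0.14 (adjusted p = 0.326), although Egln3, an oxygen sensor, was at 3.17 ± 0.19 and 2.79 ± 0.30 and Car9 at 2.29 ± 0.41 and 1.93 ± 0.33. Lipid synthesis genes had medians of 0.20 (adjusted p = 0.262) and 0.40 (adjusted p = 0.338), with Srebf1 at 2.75 ± 0.28 and 2.59 ± 0.23. Notch pathway genes had medians of -0.37 (adjusted p = 0.905) and -0.16 (adjusted p = 0.86), with Hey1 at 3.86 ± 0.19 and 3.23 ± 0.13 and Jag2 at -2.49 ± 0.20 and -2.90 ± 0.29. Retinoid and RXR genes had medians of -1.16 (adjusted p = 0.0756) and -0.14 (adjusted p = 0.338), and immediate early genes, which respond to tissue handling, -0.23 (adjusted p = 0.843) and -0.46 (adjusted p = 0.65). In untreated tumours the macrophage, T and NK cell, and B and plasma cell medians were 0.05 (adjusted p = 0.469), -0.18 (adjusted p = 0.425) and 0.05 (adjusted p = 0.726). There the signs differ for 3 lists: the B and plasma cell median is above 0 and its test and mean point down, the Notch median is below 0 and its test and mean point up, and the macrophage mean alone is below 0.

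The interferon list was lowest in a single tumour of each group, with a median of 0.05 in DMBA 1 (1.55 to 2.52 in the rest) and -0.12 in untreated 2 (0.91 to 2.29 in the rest). Antigen presentation genes were also lowest in untreated 2, with a shift of -0.78 (1.17, the rest between 1.56 and 2.31) beside an interferon shift of -1.46. In DMBA 1 they shifted by -0.38 beside -1.98, but their median of 1.88 lay inside the range of the rest (1.84 to 2.62). B and plasma cell genes shifted by -0.26 in untreated 2 and 0.005 in DMBA 1. The larger of the macrophage and T and NK cell shifts was only 0.07 times the interferon shift in DMBA 1 and 0.149 times in untreated 2. These tumours were chosen as the lowest on the interferon list, which favours small ratios, and the limit for the ratio was set afterwards. The ratios show that neither immune list fell as far, but they cannot decide whether fewer immune cells played a part. The values argue against scaling of the array, since quantile normalization left 0.987 and 0.986 times the shift. The SD of all values was 1.34 on DMBA 1, inside the range of the others (1.32 to 1.43). On untreated 2 it was 1.32, below the others (1.36 to 1.45), so there the SD does not speak against scaling. No other biological explanation was tested, so a difference in interferon signalling between these tumours is a hypothesis that may be followed up.

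Single arrays far from the rest of their group may reflect readings of single features. Among 33653 features of the DMBA table, 117 read at least 4 from the other tumours on 1 array while those lay within 2 of each other, 97 of them downward. Of 70 such features with another feature of the gene, 15 (21.43%, 95% interval 12.5 to 32.9) had one that deviated the same way by at least 1. In the untreated table only 7 features of 18658 did so, 2 of them with another feature and 0 seen in it (0%), which is too few to decide. No biological explanation was tested.

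Untreated 2 and 6 deviated together from their group. The correlation across genes of their deviations from the group mean was 0.199, against -0.428 to 0.062 for the other pairs, and unstructured arrays would give -0.20. The labels put both in the same group as the rest, and nothing in them sets these tumours apart.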
